A study of Homo sapiens with 8 samples.

How the data were processed

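RNA was measured in MCF10A cells, which the labels place under mammary epithelial origin and give the cell type breast cancer, although the line is a non-transformed one. There were 8 libraries of 50-bp paired-end reads from a HiSeq2500, 2 with a scramble shRNA, 2 described as HER2 overexpression and 4 with an shRNA against PHF8. The protocol names a total RNA kit with ribosomal depletion, while another label field names polyA RNA. A PLCG2 transcript that shares 3.32% of its 31-base words with 7SK RNA, which has no polyA tail, took 1.68% of all counts. No label gives a library or sequencing batch, and replicate numbers 1 and 2 stand in every group. The labels do not say whether HER2 cells carried a control shRNA or whether PHF8 shRNA cells carried the HER2 construct.

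The submitters' processing notes name kallisto and GRCh38, without a version of the tool or of the annotation. Per the file headers, the deposited tables hold 1 estimate per transcript and library. The deposited estimated counts are expected counts from kallisto and were not normalized. The deposited TPM, computed by the authors with kallisto, was not used in any test. The deposited columns of transcript length and effective length hold other values, in bases, and effective length entered 1 alternative as an offset. Of 173259 transcripts, 159239 matched GENCODE release 29 by identifier, and the 14020 unmatched ones, 1.96 to 2.38% of the counts of a library, were left out. Counts were summed to 34500 genes and rounded. Estimated counts per library were 22994068, 25137111, 23472740 and 23460289 for scramble, HER2, PHF8 shRNA_1 and PHF8 shRNA_2 replicate 1, and 24068755, 25195309, 22149484 and 23707252 for scramble, HER2, the unnumbered PHF8 shRNA and PHF8 shRNA_2 replicate 2. MTRNR2L genes, which resemble mitochondrial ribosomal RNA, took 5.12% (HER2 replicate 1) to 14.7% (the unnumbered library) of the counts.

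Differential expression was tested with edgeR 4.0.16 in R 4.3.3, with TMM factors (0.951 to 1.05), filterByExpr, glmQLFit and glmQLFTest. All 8 libraries entered 1 fit of 3 groups, since 2 libraries per control group leave few degrees of freedom for separate fits. The 3 contrasts were HER2 vs scramble, PHF8 shRNA vs scramble and PHF8 shRNA vs HER2. The constructs were compared in a fit of 4 groups that set shRNA_2 apart from the shRNA_1 and unnumbered libraries. The test covered 15436 genes, p was adjusted by Benjamini-Hochberg over them, and a gene was called at an adjusted p under 0.05. Replicates enter as independent libraries. CPM values are TMM-scaled, errors are SDs over libraries, and the SE of a log2 fold change comes from the fit. The common coefficient of variation was 0.176. PHF8 was also tested with an exact permutation over the 70 splits of 4 against 4 libraries.

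On simulated data with 200 changed genes, the same tests recovered 8.96% of genes changed 1.5-fold, 40.3% of those changed 2-fold and 81.8% of those changed 4-fold in HER2 vs scramble, 19.4, 65.7 and 83.3% in PHF8 shRNA vs scramble, 13.4, 61.2 and 80.3% in PHF8 shRNA vs HER2, and 7.46, 49.3 and 78.8% between the constructs. False calls made up 4.40, 7.44, 6.36 and 6.25% of the calls in the same order, so 1.5-fold changes are mostly missed at this depth and number of libraries. Overlaps between contrasts that share a group were set against 30 simulations of unchanged libraries on the same shared group and against the product of the list sizes.

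Gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, beside an estimated correlation and fry, and adjusted over the 27 lists within a comparison. The lists were ERBB receptors and ligands, HER2 amplicon neighbours, ERK pathway output, interferon response, inflammatory cytokines and NF-kB targets, mesenchymal genes, epithelial junctions, basal and luminal epithelial markers, cornified envelope and squamous differentiation, mitosis genes, DNA replication genes, p53 targets, cholesterol synthesis, glycolysis and hypoxia targets, unfolded protein and integrated stress response, heat shock genes, TGF-beta targets, proteases of invasion, apoptosis regulators, JmjC demethylases and PHF8-linked chromatin genes, replication-dependent histones, mitochondrially encoded genes, cytosolic ribosomal proteins, and fibroblast, blood cell and endothelial markers. Of 15 listed fibroblast markers 6 also stand in the mesenchymal list.

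Groups, the tests of the comparisons, the gene lists above, the rule for named genes and the alternatives were fixed before the data were examined. Exceptions were 2 added alternatives and the tests, simulations and gene naming that the closing sections give as chosen after the results were seen. The closing sections also test gene lists that are not among those above. Named genes were PHF8 and ERBB2, the 10 largest rises and 10 largest falls of each of the 3 comparisons, up to 4 members of each list with the smallest adjusted p, and the 5 genes with the smallest adjusted p between the constructs. Rises, falls and construct genes had to be called, protein coding, at a mean log2 CPM of at least 1 and with no overlap between the groups' libraries. Not every gene that the rule selects is described. For each named gene the share of 31-base words found in transcripts of other genes was computed from the reference, and 14 of 134 genes shared over 20%, since kallisto divides such reads by its model.

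The alternatives were RLE or upper quartile factors in place of TMM, no low-count filter or at least 1 CPM in all libraries of a group, DESeq2 1.42.0, limma-voom, the replicate number as a block, protein-coding genes alone, effective length as an offset, 4 groups in the fit, only the 2 groups compared, either set of PHF8 shRNA libraries alone, each of the 8 libraries left out, and, for lists, an estimated correlation or fry. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the counts and the figures. A filter and a pseudocount for TPM had been planned for the case of files without counts and were not needed.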

Results

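The data are RNA-seq transcript abundances from MCF10A, a non-transformed human mammary epithelial cell line that grows in medium with EGF, insulin, hydrocortisone and cholera toxin. The 8 libraries fall into 3 groups. There are 2 from cells with a scramble shRNA and 2 from cells described as overexpressing HER2, the receptor tyrosine kinase encoded by ERBB2. The other 4 come from cells with an shRNA against PHF8, a histone demethylase of the JmjC family. Of the PHF8 shRNA libraries, 1 is labelled shRNA_1, 2 are labelled shRNA_2 and 1 carries no construct number. Total estimated counts per library ranged from 22149484 in the unnumbered PHF8 shRNA library to 25195309 in HER2 replicate 2. The labels speak of biological duplicates without saying how the cultures were kept apart, so p-values measure the spread between these libraries, which may be technical in part.

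The targeted genes were examined first. ERBB2 (17:39687914-39730426, plus strand, GRCh38) stood at 113 ± 3.14 CPM (SD, n = 2) in scramble, 9450.4 ± 3729 CPM (SD, n = 2) in HER2 and 12374 ± 3045 CPM (SD, n = 4) in PHF8 shRNA libraries. The single values were 115 and 111 CPM in scramble, 6814 and 12087 CPM in HER2 replicates 1 and 2, 11885 CPM with shRNA_1, 16288 CPM in the unnumbered library, and 8874 and 12448 CPM with shRNA_2. ERBB2 thus lay 83.6-fold above scramble in HER2 (log2 fold change 6.39, SE 0.41, adjusted p = 0.000215) and 109.5-fold above scramble in PHF8 shRNA (log2 fold change 6.77, SE 0.41, adjusted p = 0.000149). PHF8 shRNA and HER2 did not differ detectably in ERBB2 (log2 fold change 0.39, SE 0.28, adjusted p = 0.485). The labels do not say whether the PHF8 shRNA cells carry the HER2 construct, and all 4 had ERBB2 at the level of the HER2 libraries, so PHF8 shRNA is compared with both other groups.

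PHF8 (X:53936676-54048958, minus strand) was measured at 23.8 ± 1.70 CPM (SD, n = 2) in scramble and 20.7 ± 0.347 CPM (SD, n = 2) in HER2. It was at 16.7 ± 0.593 CPM (SD, n = 2) in the shRNA_1 and unnumbered libraries and 8.84 ± 0.173 CPM (SD, n = 2) with shRNA_2. The 4 PHF8 shRNA libraries all lay below the other 4, 1.82-fold on average (two-sided exact permutation test, p = 0.0286, the smallest p that 4 against 4 allows). In the fit across all genes PHF8 did not pass the threshold against scramble (log2 fold change -0.90, SE 0.26, adjusted p = 0.0592) or against HER2 (log2 fold change -0.70, SE 0.26, adjusted p = 0.223). Without PHF8 shRNA_1 replicate 1, or with DESeq2, limma-voom, no low-count filter or a transcript length offset, it did pass against scramble, at log2 fold changes of -1.08, -0.88, -0.98, -0.91 and -0.96. The remaining PHF8 was lower with shRNA_2 than in the other 2 PHF8 shRNA libraries (log2 fold change -0.92, SE 0.13, adjusted p = 0.010). HER2 and scramble did not differ detectably (log2 fold change -0.20, adjusted p = 0.786).

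**Figure D1:**
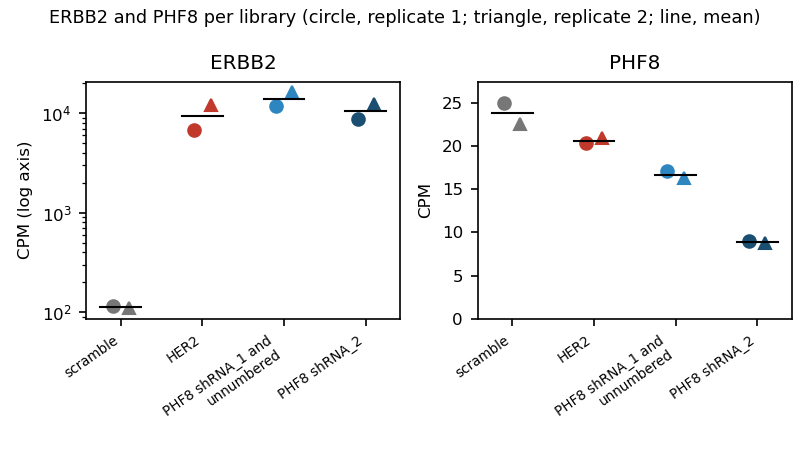
ERBB2 and PHF8 in CPM (counts scaled to library size) for each of the 8 libraries, with a log axis for ERBB2, circles for replicate 1, triangles for replicate 2 and a line at the mean. ERBB2 lies between 111 and 115 CPM in scramble and between 6814 and 16288 CPM in the HER2 and PHF8 shRNA libraries, and PHF8 is lowest with shRNA_2, at 8.72 and 8.97 CPM.

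HER2 was compared with scramble to ask what changed in cells with the HER2 construct. Neutrophil-attracting chemokines showed some of the largest rises. CXCL8, encoding interleukin 8 (4:73740506-73743716), went from 17 ± 2.28 CPM (SD, n = 2) to 159 ± 23.7 CPM (SD, n = 2) (log2 fold change 3.22, SE 0.21, adjusted p = 0.000215). CXCL1 rose 13-fold from 16.3 ± 0.592 to 212 ± 60.8 CPM, and CXCL3 rose 9.14-fold. PTGS2, the inducible cyclooxygenase, rose 4.16-fold. Of the list of inflammatory cytokines and NF-kB targets, 9 of 31 measured members rose and 0 fell (19 higher and 0 lower adjusted over the list alone; median log2 fold change 0.98, camera adjusted p = 7.20e-11, adjusted p = 0.137 with an estimated correlation). INHBA, a subunit of activin, rose 7.89-fold to 101 ± 66.5 CPM, and IL7R, the interleukin 7 receptor chain, 6.11-fold. The tests gave 146 genes higher and 125 lower among 15436, in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

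Among growth factor receptors and their feedback genes, AREG, encoding the EGFR ligand amphiregulin, rose 3.0-fold from 330.1 ± 23.5 to 991 ± 176 CPM (adjusted p = 0.0335). The receptor gene ERBB3 fell 2.29-fold from 28.2 ± 1.96 to 12.3 ± 2.14 CPM (adjusted p = 0.0237). The ERBB receptors and ligands had 2 of 15 members higher, ERBB2 itself and AREG, and 1 lower (5 and 2 adjusted over the list alone; median 0.26, camera adjusted p = 0.118). Genes of ERK pathway output, which record signalling through MAP kinases, rose in 4 of 22 cases and fell in 0 (9 and 1 adjusted over the list alone; median 0.35, camera adjusted p = 0.000101, adjusted p = 0.370 with an estimated correlation). They were the feedback inhibitor SPRY4 (2.17-fold), the phosphatases DUSP6 (2.03-fold) and DUSP4 (1.82-fold), and PHLDA1 (1.63-fold). DUSP6 shares 38.5% of its 31-base words with an overlapping transcript, so its count is uncertain. GRB7, which lies beside ERBB2 on chromosome 17, fell 2.33-fold to 16.1 ± 5.89 CPM. It was the only called gene of 8 measured HER2 amplicon neighbours (0 and 1 adjusted over the list alone; median -0.09, camera adjusted p = 0.665).

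The lists of DNA replication genes and histones were higher as sets, with the preset correlation. Of 42 DNA replication genes 4 rose and 0 fell (23 and 0 adjusted over the list alone; median 0.44, camera adjusted p = 4.29e-14, adjusted p = 0.370 with an estimated correlation). The rises were FEN1 (1.90-fold), E2F1 (1.89-fold), MCM10 (1.76-fold) and CDC45 (1.59-fold). Of 44 replication-dependent histones 8 rose and 0 fell (34 and 0 adjusted over the list alone; median 0.54, camera adjusted p = 9.90e-20, adjusted p = 0.370 with an estimated correlation). Among them were HIST1H3A (1.78-fold), HIST1H2BI (1.71-fold) and HIST1H2AM (1.61-fold). HIST1H2AM overlaps HIST1H3J and shares 87.1% of its words with it, and HIST1H2BI shares 25.1% with other histone genes, so both are uncertain. The mitosis genes had 0 of 36 called, and a median of 0.19 (camera adjusted p = 0.000221, adjusted p = 0.614 with an estimated correlation).

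The 10 largest falls by the naming rule held genes of several kinds. GLUL, encoding glutamine synthetase (1:182381704-182392206), fell 5.06-fold from 1229 ± 34.0 CPM (SD, n = 2) to 243 ± 74.0 CPM (SD, n = 2) (log2 fold change -2.34, SE 0.22, adjusted p = 0.00219). GREB1, an oestrogen-responsive gene, fell 5.29-fold, HPGD, which degrades prostaglandins, 5.04-fold, the water and glycerol channel AQP3 4.66-fold, RGCC 6.09-fold and the epithelial transcription factor ELF3 9.14-fold (20.3% of its words are shared). The pro-apoptotic BH3-only genes HRK (9.93-fold), BMF (3.38-fold) and BCL2L11, which encodes BIM (2.02-fold, from 23.0 ± 3.0 to 11.3 ± 0.411 CPM), all fell. They were the 3 called members of 29 apoptosis regulators (1 and 4 adjusted over the list alone; median 0.20, camera adjusted p = 0.588). PBX2 fell 72.3-fold, but its 2 scramble values of 20.1 and 6.45 CPM lay far apart and 32.1% of its words are shared, chiefly with the pseudogene PBX2P1, so it is uncertain.

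Of 32 epithelial junctions genes 4 fell and 0 rose (0 and 8 adjusted over the list alone; median -0.51, camera adjusted p = 3.32e-06, adjusted p = 0.383 with an estimated correlation). They were CLDN1 of tight junctions (4.44-fold), PKP2 (2.17-fold) and DSC2 (2.13-fold) of desmosomes, and CRB3 of the apical polarity complex (2.07-fold). Of 35 mesenchymal genes 5 rose and 0 fell (9 and 0 adjusted over the list alone; median 0.48, camera adjusted p = 6.57e-05, adjusted p = 0.370 with an estimated correlation). Among them were CDH2, encoding N-cadherin (2.68-fold), the transcription factor ZEB1 (2.64-fold), COL6A1 (2.66-fold) and WNT5A (2.42-fold). The luminal markers ELF3 and GATA3 (2.21-fold) fell, 2 of 19 measured (0 and 4 adjusted over the list alone; median -0.25, camera adjusted p = 0.0202, adjusted p = 0.526 with an estimated correlation). The basal epithelial markers had 0 of 24 higher and 0 lower (1 and 1 adjusted over the list alone; median 0.15, camera adjusted p = 0.815). Of 26 cornified envelope and squamous differentiation genes 4 rose and 0 fell (6 and 2 adjusted over the list alone; median 0.79, camera adjusted p = 0.0304, adjusted p = 0.695 with an estimated correlation). These were SERPINB4 (19.2-fold, from 0.0879 ± 0.0651 to 1.76 ± 0.431 CPM), KRT6A (2.02-fold), S100A8 and S100A9. SERPINB4 and KRT6A share 33.9% and 44.0% of their words with close paralogs and are uncertain.

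HER2 replicate 1 stood apart from replicate 2. The SD over genes of the log2 difference between the HER2 libraries was 0.700, against 0.443, 0.578 and 0.418 for the scramble, the shRNA_1 and unnumbered, and the shRNA_2 pairs. Several rises rested mostly on replicate 1. FPR1, a formyl peptide receptor gene, was at 32.1 CPM in replicate 1 and 6.35 CPM in replicate 2, TNFAIP6 at 39.2 and 6.35 CPM, and S100A8 at 418 and 89.1 CPM. S100A9 was at 969.7 and 247 CPM and SRGN at 57.6 and 18.6 CPM, although both replicates exceeded both scramble libraries in each gene. The mitochondrially encoded genes had 0 of 13 members called and were negative in 13 of 13 (median -0.86, camera adjusted p = 6.57e-05, adjusted p = 0.526 with an estimated correlation). They took 0.309% of counts in HER2 replicate 1 and 0.565% in replicate 2, against 0.740% and 0.632% in scramble.

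The other lists with camera adjusted p under the threshold had few single genes called. The list of proteases of invasion had 2 of 28 members higher and 0 lower (5 and 1 adjusted over the list alone, median 0.50, camera adjusted p = 0.000810). The 2 were the protease inhibitor gene SERPINE2 (3.20-fold) and the protease gene HTRA1 (1.82-fold). Of the glycolysis and hypoxia targets, SLC2A3, a glucose transporter gene (5.51-fold; 30.4% of its words are shared, chiefly with SLC2A14), and ANGPTL4 (3.03-fold) rose. They were 2 of 35, and 0 fell (6 and 1 adjusted over the list alone; median 0.27, camera adjusted p = 6.57e-05). The heat shock genes had 2 of 18 higher, DNAJA1 (1.62-fold) and STIP1 (1.59-fold), and 0 lower (5 and 0 adjusted over the list alone; median 0.30, camera adjusted p = 9.47e-05). Of the TGF-beta targets 2 of 27 rose, INHBA and ANGPTL4, and 0 fell (2 and 1 adjusted over the list alone; median 0.28, camera adjusted p = 0.0202). INSIG1, of sterol feedback, rose 2.50-fold as the only called gene of 24 in cholesterol synthesis (1 and 0 adjusted over the list alone; median 0.19, camera adjusted p = 0.00488). The unfolded protein and integrated stress response genes had 0 of 32 called (0 and 0 adjusted over the list alone; median 0.27, camera adjusted p = 0.00488). The cytosolic ribosomal proteins had 0 of 55 (0 and 0 adjusted over the list alone; median -0.09, camera adjusted p = 0.0453). With an estimated correlation the adjusted p values of these 7 lists were 0.383, 0.370, 0.370, 0.633, 0.526, 0.526 and 0.833 in that order.

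Lists that did not pass were the interferon response (0 of 36 higher and 0 lower, median -0.01, camera adjusted p = 0.665) and p53 targets (1 of 30 higher and 0 lower, median 0.04, camera adjusted p = 0.239). Another was the list of JmjC demethylases and PHF8-linked chromatin genes (1 of 27 higher and 0 lower, median -0.09, camera adjusted p = 0.665; the called gene is E2F1). Nor did markers of cell types that could be mixed in, namely fibroblast markers (1 of 8 higher and 0 lower, median 0.28, camera adjusted p = 0.342; the called gene is DCN), blood cell markers (0 of 4 higher and 0 lower, median -0.46, camera adjusted p = 0.764) and endothelial markers (0 of 6 higher and 0 lower, median -0.48, camera adjusted p = 0.574). Adjusted over the list alone, 1 gene was higher and 0 lower in each of the p53, JmjC, fibroblast and blood lists, and 0 in the interferon, endothelial, mitosis and mitochondrial lists. The test pointed up with a negative median and mean for the interferon response, and the median and mean of the apoptosis regulators differed in sign. The counts of called genes rested on the scramble libraries: without scramble replicate 1, 3 genes were higher and 3 lower, and without replicate 2, 8 and 6. Further, 86 were higher without PHF8 shRNA_2 replicate 2 and 271 lower without HER2 replicate 2. Of the named calls, 3 remained without scramble replicate 1 and 7 without replicate 2, and other settings gave from 31 higher and 39 lower with only the 2 groups in the fit to 518 and 359 with DESeq2.

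**Figure D2:**
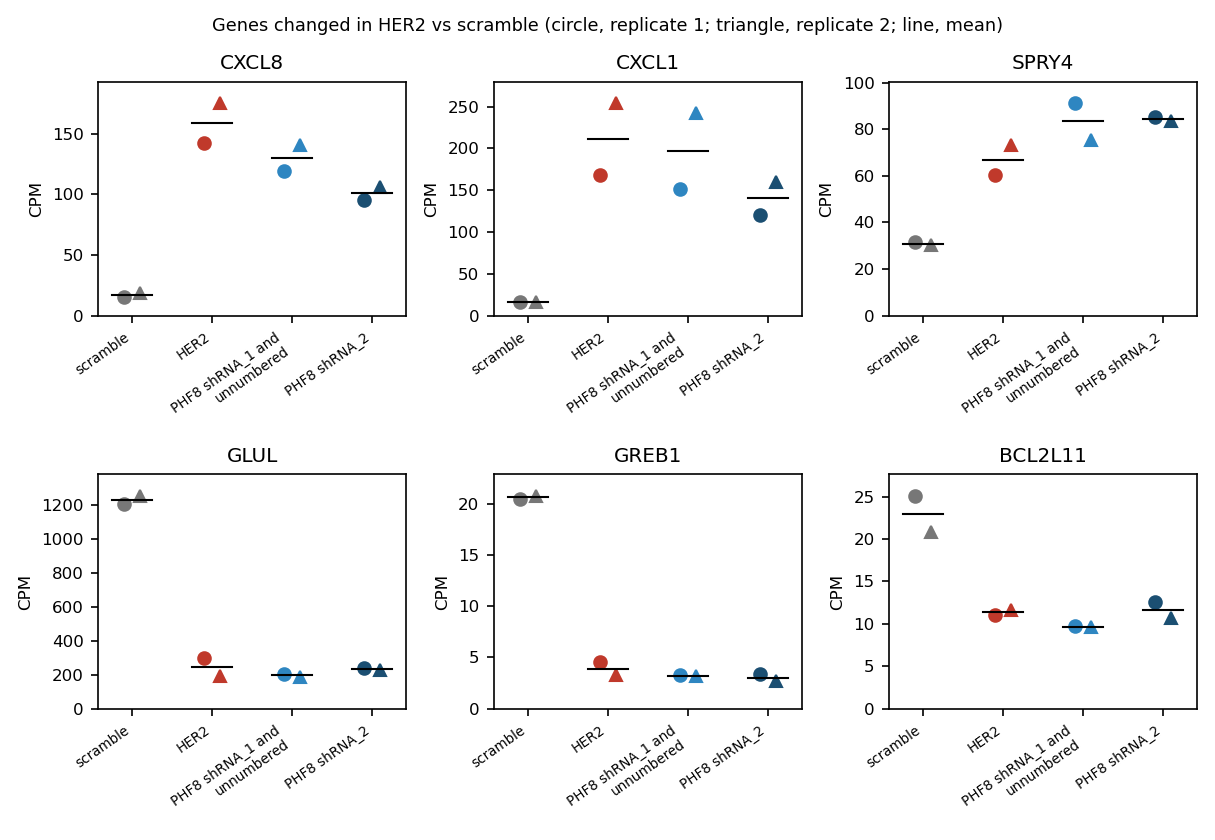
CPM per library of 3 genes that rose (CXCL8, CXCL1, SPRY4) and 3 that fell (GLUL, GREB1, BCL2L11) in HER2 vs scramble, with circles for replicate 1, triangles for replicate 2 and a line at the mean. In each panel the PHF8 shRNA libraries lie on the HER2 side of scramble, for example GLUL at 215 ± 24.3 CPM in PHF8 shRNA.

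PHF8 shRNA was then compared with scramble, which sets libraries with both high ERBB2 and lower PHF8 against libraries with neither. The same chemokines rose again: CXCL1 10.3-fold to 169 ± 52.1 CPM (SD, n = 4) (log2 fold change 3.37, SE 0.31, adjusted p = 0.000539), CXCL3 9.21-fold and CXCL8 6.79-fold. IL1B, the cytokine interleukin 1 beta, rose 10.5-fold, NLRP3, the inflammasome sensor, 8.21-fold, INHBA 11.7-fold and CSF3 4.87-fold. Of the inflammatory cytokines and NF-kB targets, 19 of 31 members rose and 2 fell (21 and 2 adjusted over the list alone; median 1.41, camera adjusted p = 3.65e-10, adjusted p = 0.153 with an estimated correlation). The nicotinic receptor gene CHRNA9 (16.8-fold), the growth factor gene BMP6 (9.87-fold), GRAMD1B (9.30-fold) and CD163L1 (8.31-fold) were among the 10 largest rises by the naming rule. In all, 668 genes were higher and 703 lower of 15436 (edgeR, adjusted p).

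The largest falls by the naming rule included KLF15 and ELF3. KLF15 fell 12.5-fold (log2 fold change -3.64, SE 0.37, adjusted p = 0.000843). TSC22D3, a glucocorticoid-induced gene, fell 8.82-fold. PDK4, a kinase that restrains pyruvate oxidation, fell 8.51-fold, ELF3 10.6-fold, RGCC 7.61-fold, GREB1 6.63-fold, ZNF608 7.20-fold, the alcohol dehydrogenase gene ADH1B 7.85-fold and CYP1A1, a target of the aryl hydrocarbon receptor, 7.05-fold. The apoptosis regulators had 5 of 29 members lower and 3 higher (3 and 5 adjusted over the list alone; median -0.00179, camera adjusted p = 0.665). BCL2L11 (2.15-fold), BMF (2.98-fold) and TNFSF10, which encodes the death ligand TRAIL (10.0-fold), were lower, and the TRAIL receptor gene TNFRSF10B was higher (1.73-fold).

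Of 22 ERK pathway output genes 11 rose and 0 fell (14 and 1 adjusted over the list alone; median 0.71, camera adjusted p = 6.60e-07, adjusted p = 0.556 with an estimated correlation). Rises included SPRY4 (2.72-fold), DUSP4 (2.36-fold), FOSL1, a component of AP-1 (2.86-fold), and CCND1, encoding cyclin D1 (1.87-fold). The ERBB receptors and ligands had 5 of 15 higher, among them AREG (2.46-fold) and EPGN (2.22-fold), and 1 lower, ERBB3 (2.21-fold; 6 and 3 adjusted over the list alone; median 0.40, camera adjusted p = 0.0891). Of DNA replication genes 15 of 42 rose and 0 fell (22 and 1 adjusted over the list alone; median 0.38, camera adjusted p = 2.29e-08, adjusted p = 0.556 with an estimated correlation). FEN1 (1.83-fold) and UHRF1 (1.80-fold; 27.3% of its words are shared) were among them. Of replication-dependent histones 13 of 44 rose and 0 fell (26 and 0 adjusted over the list alone; median 0.41, camera adjusted p = 2.28e-10, adjusted p = 0.556 with an estimated correlation). The mitosis genes had 1 of 36 higher, AURKB (1.45-fold), and 1 lower, CDC25C (1.38-fold; 1 and 1 adjusted over the list alone; median -0.10, camera adjusted p = 0.195).

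Of epithelial junctions 8 of 32 fell and 0 rose (0 and 12 adjusted over the list alone; median -0.50, camera adjusted p = 2.98e-06, adjusted p = 0.556 with an estimated correlation). They included the desmosomal DSC2 (1.78-fold), DSC3 (2.45-fold) and PKP2 (2.21-fold) and the tight junction gene TJP3 (8.88-fold). Of mesenchymal genes 9 of 35 rose and 2 fell (10 and 2 adjusted over the list alone; median 0.62, camera adjusted p = 0.000520, adjusted p = 0.556 with an estimated correlation). ZEB1 (2.49-fold) and CDH2 (2.56-fold) were among the rises, and TWIST1, also a mesenchymal transcription factor, fell 1.92-fold, from 20.8 ± 1.29 to 10.8 ± 0.567 CPM. The basal epithelial markers had 2 of 24 higher and 1 lower (3 and 4 adjusted over the list alone; median -0.01, camera adjusted p = 0.747), with KRT15 the one that fell (5.38-fold). The luminal epithelial markers had 1 of 19 higher and 3 lower (2 and 4 adjusted over the list alone; median -0.05, camera adjusted p = 0.290). The cornified envelope and squamous differentiation genes had 2 of 26 higher and 1 lower (3 and 1 adjusted over the list alone; median 0.47, camera adjusted p = 0.136).

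Of proteases of invasion 3 of 28 rose and 1 fell (3 and 1 adjusted over the list alone; median 0.50, camera adjusted p = 0.00671, adjusted p = 0.556 with an estimated correlation). The rises were the urokinase gene PLAU (2.27-fold), its receptor gene PLAUR (2.95-fold) and the protease inhibitor gene SERPINE2 (2.63-fold). PLAU shares 24.1% of its words with an overlapping gene. The p53 targets had 4 of 30 higher and 6 lower (4 and 11 adjusted over the list alone; median -0.31, camera adjusted p = 0.0211, adjusted p = 0.737 with an estimated correlation). TP53INP1 was lower (2.16-fold) and TNFRSF10B higher. Of the glycolysis and hypoxia targets 6 of 35 rose, SLC2A3 (6.14-fold), ANGPTL4 (4.23-fold) and NDRG1 (1.95-fold) among them, and 0 fell (7 and 0 adjusted over the list alone; median 0.21, camera adjusted p = 0.00671, adjusted p = 0.556 with an estimated correlation). The TGF-beta targets had 5 of 27 higher and 0 lower (9 and 1 adjusted over the list alone; median 0.47, camera adjusted p = 0.000731, adjusted p = 0.556 with an estimated correlation). The unfolded protein and integrated stress response genes had 4 of 32 higher, MANF among them (1.61-fold), and 0 lower (8 and 0 adjusted over the list alone; median 0.32, camera adjusted p = 0.00182, adjusted p = 0.556 with an estimated correlation). For cholesterol synthesis it was 1 of 24 higher and 0 lower (1 and 0 adjusted over the list alone; median 0.22, camera adjusted p = 0.00671, adjusted p = 0.646 with an estimated correlation). The cytosolic ribosomal proteins had 0 of 55 called and were negative in 55 of 55 (0 and 0 adjusted over the list alone; median -0.28, camera adjusted p = 2.88e-07, adjusted p = 0.737 with an estimated correlation).

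In the list of JmjC demethylases and PHF8-linked chromatin genes 1 gene fell and 2 rose of 27 (2 and 2 adjusted over the list alone; median 0.01, camera adjusted p = 0.791). The fall was in ZNF711, an X-linked zinc finger gene whose protein is known to bind PHF8, from 7.71 ± 0.351 CPM (SD, n = 2) to 3.29 ± 0.310 CPM (SD, n = 4) (log2 fold change -1.23, SE 0.18, adjusted p = 0.00408). It stood at 6.44 ± 0.307 CPM in HER2, where the difference from PHF8 shRNA missed the threshold (adjusted p = 0.0693). Of the interferon response genes OAS1 fell (3.13-fold), 1 of 36, and 0 rose (0 and 0 adjusted over the list alone; median 0.04, camera adjusted p = 0.606). The heat shock genes had 3 of 18 higher and 0 lower (4 and 0 adjusted over the list alone; median 0.20, camera adjusted p = 0.152). The mitochondrially encoded genes had 0 of 13 higher and 0 lower (median 0.41, camera adjusted p = 0.195) and the HER2 amplicon neighbours 0 of 8 higher and 1 lower, GRB7 (2.65-fold; median -0.05, camera adjusted p = 0.580). Markers of other cell types had 0 of 8 higher and 0 lower for fibroblasts (median 0.09, camera adjusted p = 0.631) and 1 of 4 higher and 0 lower for blood cells (median 0.05, camera adjusted p = 0.631). They had 1 of 6 higher and 0 lower for endothelium (median 0.02, camera adjusted p = 0.773). Adjusted over the list alone, the blood and endothelial lists had 1 higher and 0 lower, the amplicon list 0 and 1, and the mitochondrial and fibroblast lists 0 and 0. Median and mean differed in sign for the heat shock, basal and JmjC lists, and the test pointed up in all 3. Without scramble replicate 1 the counts were 24 higher and 48 lower, without scramble replicate 2 46 and 90, and without PHF8 shRNA_2 replicate 2 344 and 370. Of the named calls 14 and 27 remained without scramble replicate 1 and 2, and DESeq2 gave 1167 higher, the fit of only the 2 groups 1030 higher, and the transcript length offset 397 higher and 416 lower.

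Calls of the comparisons with scramble overlapped. Of the 271 genes called in HER2 vs scramble, 232 were called in the same direction in PHF8 shRNA vs scramble, and 0 in the opposite direction. They were 118 rises, such as CXCL1, SPRY4 and SERPINE2, and 114 falls, such as GREB1, ELF3 and ERBB3. Simulated unchanged groups against the same scramble libraries gave a mean of 0.1 and at most 1, and independent lists would share 12. Unchanged groups yield few calls, so the simulated count is low by design and does not measure what the shared controls add. The 2 scramble libraries were not split, since each part would hold 1 library, so part of the excess may come from the shared controls. Across genes the correlation of the fold changes was 0.588 (simulated mean 0.583) and their covariance 0.244 (simulated mean 0.101, a difference of 0.143). Genes are not independent replicates. The overlap was 6 genes without scramble replicate 1, 12 without scramble replicate 2 and 139 without PHF8 shRNA_2 replicate 2, and 157 to 328 with each of the others left out. It was 610 with DESeq2, 407 without a low-count filter, 418 with 4 groups, 374 with only shRNA_2, 118 with the transcript length offset and 60 with only the 2 groups compared.

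**Figure D3:**
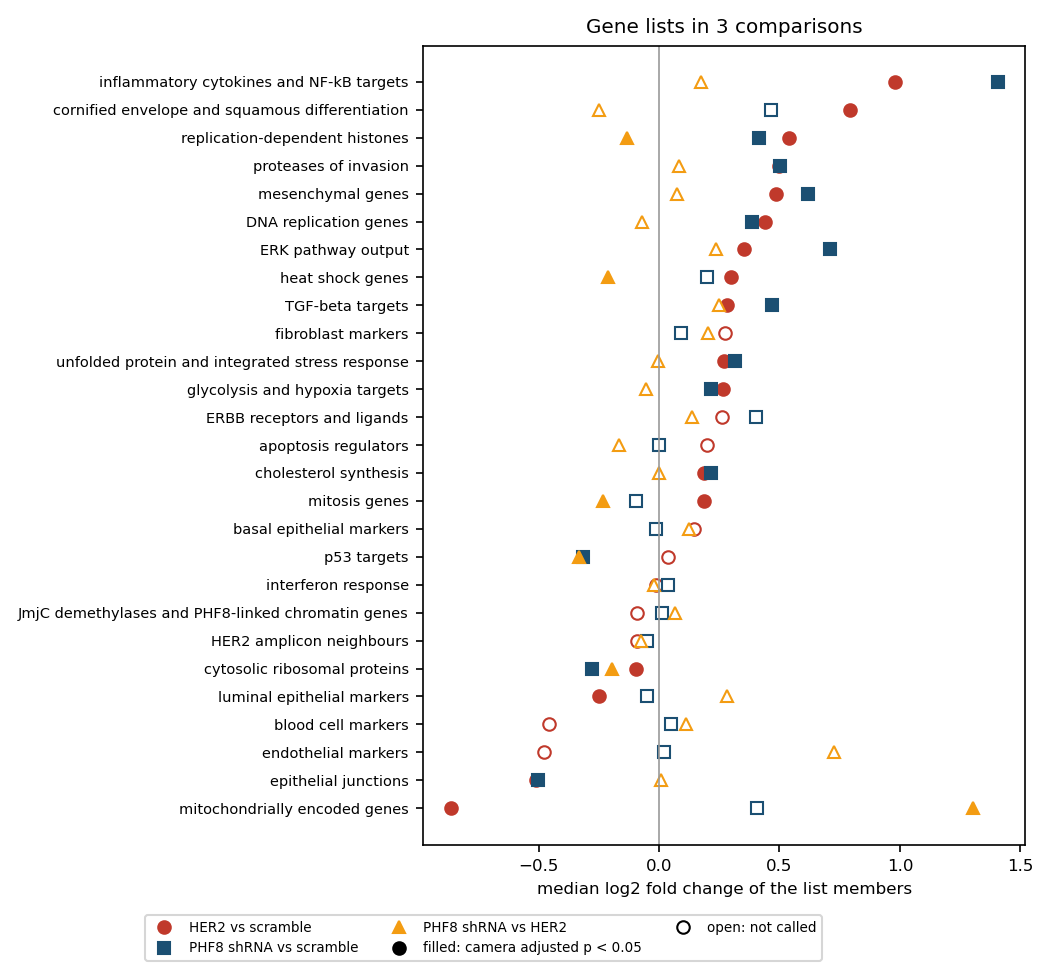
Median log2 fold change of each of the 27 gene lists in HER2 vs scramble (circles), PHF8 shRNA vs scramble (squares) and PHF8 shRNA vs HER2 (triangles), filled where camera with its preset correlation passed the threshold. The inflammatory cytokines and NF-kB targets lie at 0.98 and 1.41 against scramble and at 0.17 against HER2, and with an estimated correlation no list passed in any of the 3 comparisons.

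PHF8 shRNA was compared with HER2, groups with a like ERBB2 level, to ask what differed with the PHF8 shRNA. HER2 replicate 2 lay nearer to all 4 PHF8 shRNA libraries than to HER2 replicate 1. Chi-square per degree of freedom between its counts and theirs was 26.4 (shRNA_1), 38.3 and 27.2 (shRNA_2 replicates 1 and 2) and 54.3 (unnumbered). Against HER2 replicate 1 it was 98.9. A difference from the HER2 mean can thus come from HER2 replicate 1 rather than from the PHF8 shRNA. Genes higher in PHF8 shRNA than in both other groups included IGFBP7, an insulin-like growth factor binding protein (32.2 ± 3.37 CPM (SD, n = 4) against 16 ± 0.391 in HER2 and 14.6 ± 1.28 in scramble; log2 fold change 1.01, SE 0.13, adjusted p = 0.0408). Others were the ubiquitin-conjugating enzyme gene UBE2Z (1.73-fold), EDC3 of mRNA decapping (2.27-fold) and SUZ12, a core subunit of Polycomb repressive complex 2 (1.72-fold). So were STK40 (1.79-fold), GDPD5 (2.29-fold), CPPED1 (1.86-fold), ABHD17C (1.80-fold) and the calcium channel gene RYR2 (4.34-fold). Each of these was also called higher against scramble. Genes lower than in both other groups included the retinol dehydrogenase gene DHRS9 (2.71-fold), ASAP3 (2.28-fold) and TENT5A (1.92-fold). In all, 17 genes were higher and 20 lower (edgeR, adjusted p; upper quartile scaling gave 29 and 21, and the transcript length offset 1 and 5).

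A further set had moved in HER2 and lay nearer to scramble in PHF8 shRNA. Of the genes called in HER2 vs scramble, 11 were called in the opposite direction in PHF8 shRNA vs HER2. DCN, encoding the proteoglycan decorin, was at 48.8 ± 3.61 CPM in scramble, 109 ± 39.1 CPM (SD, n = 2) in HER2 and 38.0 ± 5.89 CPM in PHF8 shRNA (log2 fold change -1.53, SE 0.20, adjusted p = 0.0408). NAMPT, of NAD synthesis, was at 483 ± 2.37, 1088 ± 173 and 543 ± 85.2 CPM in the same order, with 29.9% of its words shared, chiefly with a pseudogene. The serine protease gene HTRA1 (2.21-fold), the adhesion receptor gene ADGRL3 (3.20-fold), the natriuretic peptide receptor gene NPR3 (3.40-fold), ACO1, which encodes an iron-regulatory protein (1.55-fold), INSIG1 (1.72-fold) and FPR1 (17.1-fold) were likewise lower than in HER2. Of the 11, INSIG1 alone was still called against scramble (1.46-fold higher). SAMD12 (4.82-fold), TNRC6B of microRNA silencing (1.61-fold) and the helicase gene HELZ (1.67-fold) were higher than in HER2. HER2 replicate 1 held the more extreme HER2 value for DCN (137 against 81.8 CPM), HTRA1 (262 against 172), NAMPT (1209.8 against 966) and FPR1 (32.1 against 6.35).

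Simulated unchanged libraries gave a mean of 0.0333 and at most 1 gene moved back, and independent lists 0.327. The simulated count is low by design, since unchanged libraries yield few calls, and does not measure what the shared HER2 libraries add. The 2 shared HER2 libraries were not split, since each part would hold 1 library, so part of the excess may come from them. The covariance of the fold changes of HER2 vs scramble and PHF8 shRNA vs HER2 across genes was -0.175, against a simulated -0.0997 (difference -0.0748), with correlations of -0.461 and -0.578. The simulations understate the spread of the HER2 pair. At a mean log2 CPM of at least 1 they put 224 genes on average over 2-fold apart in it, against 546 observed. Part or all of the difference in covariance may come from that spread, so it decides nothing. The calls of PHF8 shRNA vs HER2, DCN and NAMPT included, were fragile. Without scramble replicate 1 or 2, HER2 replicate 1, PHF8 shRNA_1 replicate 1, the unnumbered replicate 2, or PHF8 shRNA_2 replicate 1 or 2, 0 genes were called and 0 moved back. Without HER2 replicate 2, 740 were higher, 584 lower and 227 moved back. Unadjusted p was under 0.05 for 2784 genes with all libraries, DESeq2 with all libraries called 313 higher and 266 lower, and the fit of only these 2 groups called 0.

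**Figure D4:**
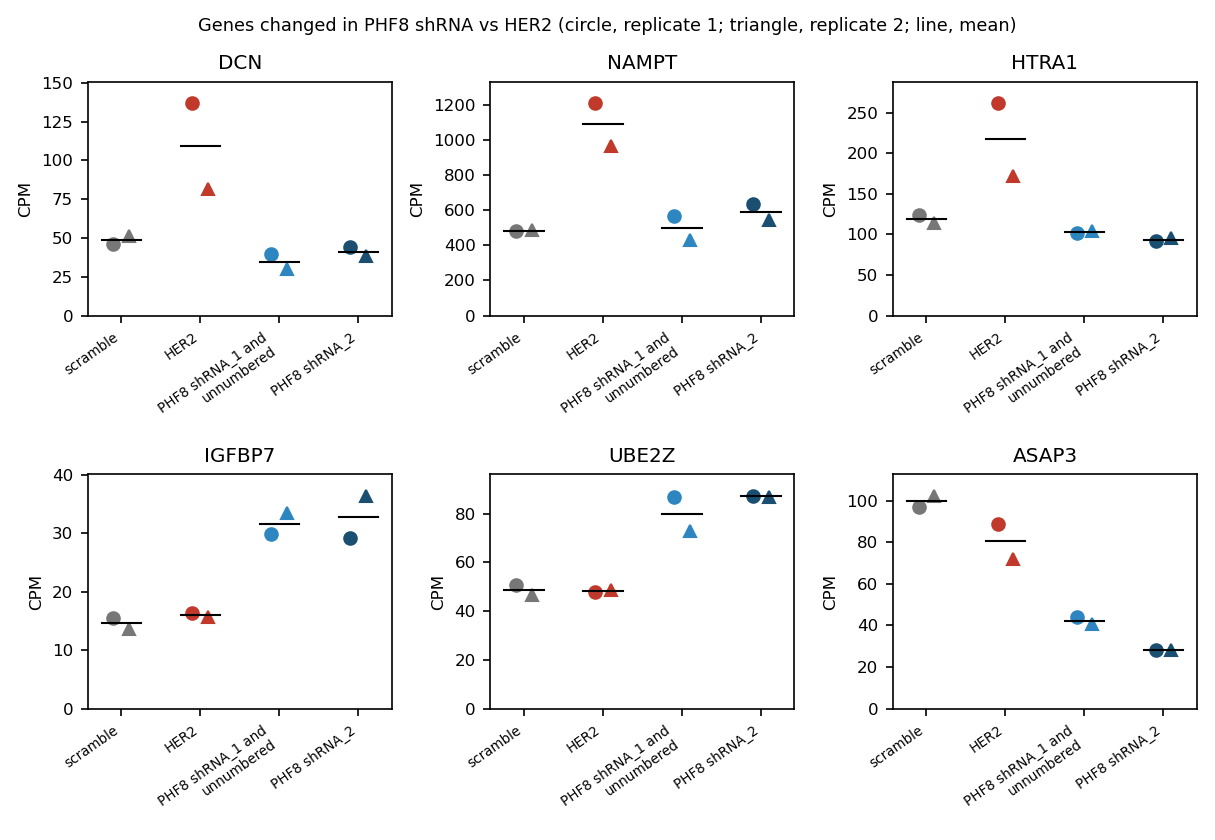
CPM per library of 6 genes called in PHF8 shRNA vs HER2, with circles for replicate 1, triangles for replicate 2 and a line at the mean. DCN, NAMPT and HTRA1 are raised in HER2 and lie near scramble in PHF8 shRNA. IGFBP7 and UBE2Z are higher in PHF8 shRNA than in both other groups, and ASAP3 is at 99.7 ± 3.70 CPM in scramble, 80.4 ± 12.1 CPM in HER2 and 35.3 ± 8.26 CPM in PHF8 shRNA.

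In lists, the mitosis genes were lower in PHF8 shRNA than in HER2 as a set (median -0.23, camera adjusted p = 4.20e-07, adjusted p = 0.960 with an estimated correlation). The mitotic kinase gene AURKA was the 1 called of 36 (96.7 ± 10.9 against 162 ± 8.45 CPM; log2 fold change -0.75, SE 0.12, adjusted p = 0.0410), and 13 were lower adjusted over the list alone. The p53 targets had 0 of 30 higher and 0 lower (3 and 10 adjusted over the list alone; median -0.33, camera adjusted p = 0.000115, adjusted p = 0.960 with an estimated correlation). The replication-dependent histones had 0 of 44 higher and 0 lower (0 and 0 adjusted over the list alone; median -0.13, camera adjusted p = 0.000899, adjusted p = 0.960 with an estimated correlation). The cytosolic ribosomal proteins had 0 of 55 higher and 0 lower (0 and 0 adjusted over the list alone; median -0.20, camera adjusted p = 0.000673, adjusted p = 0.960 with an estimated correlation). The heat shock genes had 0 of 18 higher and 0 lower (0 and 0 adjusted over the list alone; median -0.21, camera adjusted p = 0.0134, adjusted p = 0.960 with an estimated correlation). The mitochondrially encoded genes had 0 of 13 higher and 0 lower (12 and 0 adjusted over the list alone; median 1.30, camera adjusted p = 1.80e-07, adjusted p = 0.960 with an estimated correlation). Their share of counts was lowest in HER2 replicate 1 (0.309%), with the highest share in the unnumbered PHF8 shRNA library (1.03%).

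The other 21 lists did not pass in this comparison. Median log2 fold changes and camera adjusted p values were 0.14 and 0.815 for the ERBB receptors and ligands and -0.07 and 0.815 for the HER2 amplicon neighbours. They were 0.24 and 0.0881 for ERK pathway output, -0.02 and 0.919 for the interferon response, and 0.17 and 0.622 for the inflammatory cytokines and NF-kB targets. For mesenchymal genes they were 0.07 and 0.815, against 0.01 and 0.919 for epithelial junctions. The values were 0.12 and 0.919 for basal, 0.28 and 0.314 for luminal and -0.25 and 0.622 for cornified envelope genes. For DNA replication genes they were -0.07 and 0.152, for cholesterol synthesis -0.00158 and 0.839, for glycolysis and hypoxia targets -0.05 and 0.628, and for the stress response -0.00203 and 0.815. For TGF-beta targets they were 0.25 and 0.152, for proteases of invasion 0.08 and 0.919, for apoptosis regulators -0.17 and 0.548 and for JmjC demethylases and PHF8-linked chromatin genes 0.07 and 0.815. Fibroblast, blood cell and endothelial markers gave 0.20 and 0.951, 0.11 and 0.622, and 0.73 and 0.314. Single genes called in these lists were DCN, INSIG1 and HTRA1, all lower. Adjusted over the list alone, ERK output had 3 genes higher and 0 lower, the mesenchymal genes 0 and 4, the cytokine list 0 and 3, the proteases of invasion 1 and 3, and the apoptosis regulators 3 and 1. The TGF-beta targets had 2 and 1, cornified genes 1 and 2, endothelial markers 1 and 0, and the luminal, cholesterol, JmjC and fibroblast lists 0 and 1, with 0 and 0 in the other 9. The test pointed down with a positive median for the fibroblast, mesenchymal and junction lists and up with a negative median for the interferon and stress response lists. Median and mean differed in sign for the amplicon, interferon, cholesterol, glycolysis and stress response lists.

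The constructs were compared by setting the 2 shRNA_2 libraries against the shRNA_1 library and the unnumbered library, in a fit with 4 groups. ESRP1, an epithelial splicing regulator (8:94641074-94707466), was at 27.0 ± 2.50 CPM (SD, n = 2) with shRNA_2 and 1.59 ± 0.156 CPM (SD, n = 2) in the other pair (log2 fold change 4.09, SE 0.21, adjusted p = 8.55e-05). It was at 2.04 ± 0.367 CPM in HER2 and 5.48 ± 0.422 CPM in scramble. The matrix protein gene SPARC was 8.71-fold and the collagen receptor gene MRC2 4.53-fold higher with shRNA_2. EPCAM, an epithelial adhesion gene, was 2.7-fold lower, the EGFR ligand gene EREG 2.63-fold lower, and CDH1, encoding E-cadherin, 2.52-fold lower with shRNA_2. In all, 94 genes were higher and 106 lower with shRNA_2 (edgeR, adjusted p).

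IL1B (3.78-fold) and IL1A (2.05-fold) were lower with shRNA_2, and IL1RL1, an interleukin 33 receptor gene, was higher (4.74-fold). The inflammatory cytokines and NF-kB targets thus had 0 of 31 higher and 2 lower (0 and 4 adjusted over the list alone; median -0.17, camera adjusted p = 0.0507). ERK pathway output, the list that holds IL1RL1, had 1 of 22 higher and 0 lower (median -0.13, camera adjusted p = 0.177). The ERBB receptors and ligands had HBEGF (1.97-fold) and EREG lower and ERRFI1, an EGFR feedback inhibitor gene, higher (2.22-fold; 1 and 7 adjusted over the list alone; median -0.40, camera adjusted p = 0.00254, adjusted p = 0.712 with an estimated correlation). The amino acid transporter genes SLC7A5 (3.70-fold, from 1825 ± 364 to 493 ± 105 CPM) and SLC3A2 (2.69-fold) were lower, 2 of 32 stress response genes (median -0.05, camera adjusted p = 0.522). The interferon-induced BST2 (21.7-fold) and IFI44L (2.90-fold) were higher, 2 of 36 in their list (median 0.03, camera adjusted p = 0.110). In the list of proteases of invasion ADAM12 was higher (2.54-fold), and ADAM8 (3.67-fold) and the protease inhibitor gene SERPINB2 (7.79-fold) were lower. Adjusted over the list alone, 2 members were higher and 6 lower (median -0.14, camera adjusted p = 0.167). HMGCS1 of cholesterol synthesis was lower (2.30-fold; median -0.27, camera adjusted p = 0.000206, adjusted p = 0.504 with an estimated correlation). So were PLK2 of the p53 targets (1.80-fold; median -0.02, camera adjusted p = 0.330) and MFAP5 of the fibroblast markers (8.72-fold; median -0.21, camera adjusted p = 0.167).

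Of epithelial lists, junction genes had 1 of 32 higher and 2 lower (1 and 10 adjusted over the list alone; median -0.35, camera adjusted p = 8.58e-05, adjusted p = 0.712 with an estimated correlation). ESRP1 was the rise. The luminal epithelial markers had 0 of 19 higher and 2 lower, ALDH1A3 (2.61-fold; 26.1% of its words are shared) and CD24 (3.21-fold; 0 and 3 adjusted over the list alone; median -0.29, camera adjusted p = 0.00254, adjusted p = 0.336 with an estimated correlation). The basal epithelial markers had 0 of 24 higher and 0 lower (0 and 12 adjusted over the list alone; median -0.53, camera adjusted p = 1.60e-07, adjusted p = 0.336 with an estimated correlation). Cornified envelope genes had 0 of 26 higher and 1 lower, SPRR2D (15.2-fold; 29.9% of its words are shared; 0 and 11 adjusted over the list alone; median -1.54, camera adjusted p = 1.10e-07, adjusted p = 0.712 with an estimated correlation). Among mesenchymal genes SPARC was called, 1 of 35 (median 0.000787, camera adjusted p = 0.698). The other lists gave -0.11 and 0.0387 as median and camera adjusted p for mitosis genes, -0.08 and 0.0394 for DNA replication genes and 0.16 and 0.00157 for cytosolic ribosomal proteins. They were -0.08 and 0.225 for histones, -0.12 and 0.108 for heat shock genes and -0.34 and 0.221 for mitochondrial genes. Glycolysis and hypoxia targets gave -0.02 and 0.857, followed by 0.07 and 0.391 for TGF-beta targets, -0.02 and 0.620 for apoptosis regulators and -0.12 and 0.747 for the HER2 amplicon neighbours. Values were 0.07 and 0.167 for JmjC demethylases (PHF8 was the called gene), 0.06 and 0.698 for blood and 0.22 and 0.782 for endothelial markers. With an estimated correlation the adjusted p was 0.851 for mitosis genes, 0.851 for DNA replication genes and 0.851 for cytosolic ribosomal proteins, and median and mean differed in sign for glycolysis and hypoxia targets. Adjusted over the list alone, the interferon list had 3 higher and 0 lower, cholesterol synthesis 0 and 3, the mesenchymal list 2 and 0, the stress response and p53 lists 0 and 2, and endothelial markers 2 and 2. ERK output had 1 and 0, the fibroblast and apoptosis lists 0 and 1, and the amplicon and JmjC lists 1 and 1.

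**Figure D5:**
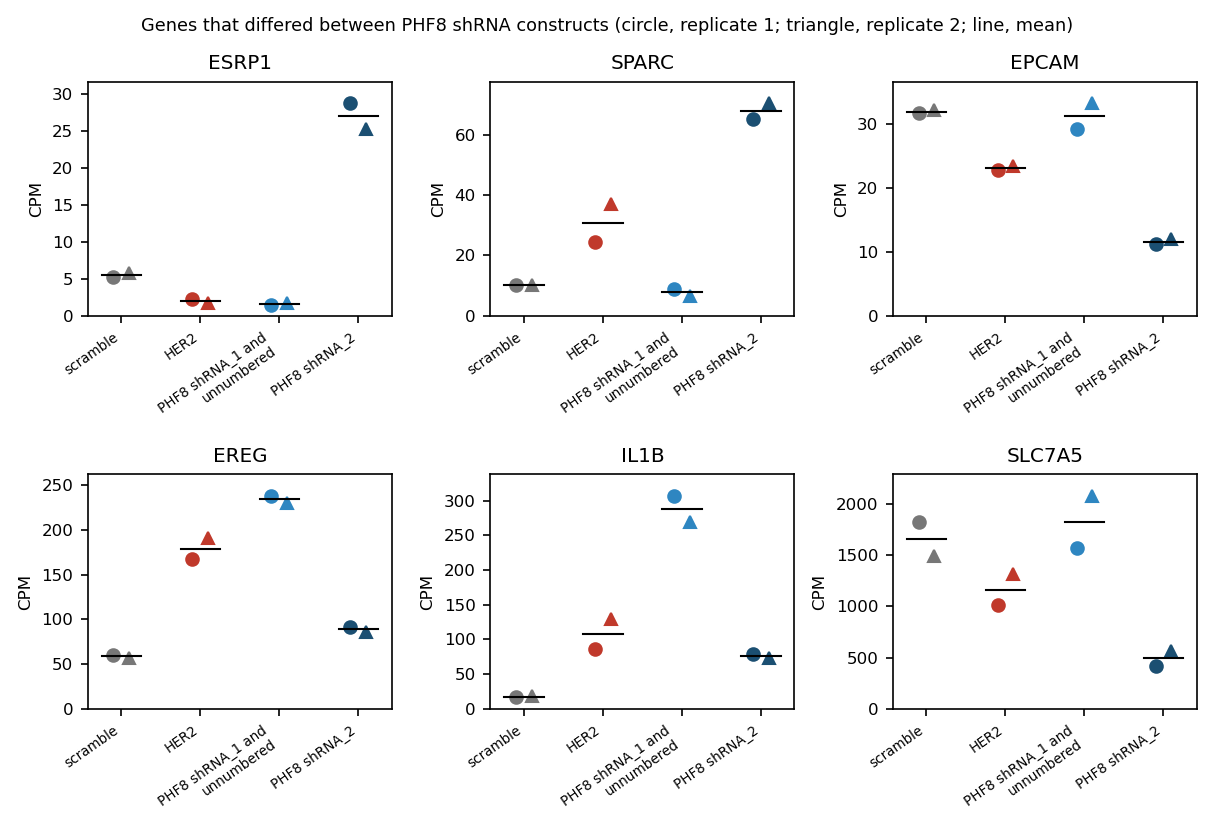
CPM per library of 6 genes that differed between shRNA_2 and the other PHF8 shRNA libraries, with circles for replicate 1, triangles for replicate 2 and a line at the mean. ESRP1 is at 27.0 ± 2.50 CPM with shRNA_2 and at 5.48 ± 0.422 CPM in scramble, 2.04 ± 0.367 CPM in HER2 and 1.59 ± 0.156 CPM in the other PHF8 shRNA libraries. IL1B is at 288 ± 27.2 CPM in the shRNA_1 and unnumbered libraries and 76.1 ± 4.41 CPM with shRNA_2.

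Against HER2, shRNA_2 gave 350 called genes and the other pair 77, of which 34 were shared in direction and 2 (SPARC and MRC2) opposed. Simulated unchanged libraries shared 0 and independent lists 0.869. With few calls in unchanged libraries, the simulated count is low by design. Part of the excess over independent lists may come from the shared HER2 libraries, which were not split, since each part would hold 1 library. The fold changes correlated at 0.555 across genes (simulated 0.487), with a covariance of 0.233 (simulated 0.0990, a difference of 0.134). These simulations understate the spread of the shared HER2 libraries, so part or all of these differences may come from it. DCN, NAMPT, IGFBP7, UBE2Z, SUZ12 and EDC3 were among the genes called in both sets of PHF8 shRNA libraries. These calls come from the fit of 4 groups, where both sets share 1 estimate of the spread. With the shRNA_2 libraries left out of the fit, the other pair had 0 genes higher and 0 lower against HER2. With only shRNA_2 they were 114 and 143. The 200 calls between constructs became 86 without scramble replicate 1, 100 without scramble replicate 2, 654 without HER2 replicate 1, and 701 without HER2 replicate 2. They became 59 without PHF8 shRNA_1 replicate 1, 58 without the unnumbered replicate 2, and 24 and 36 without shRNA_2 replicate 1 and 2. Of the other settings, no low-count filter gave 640, only the 4 PHF8 shRNA libraries 414 and DESeq2 394. The replicate number as a block gave 379 and the transcript length offset 129.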

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

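Of the tests below, the trend with GC content and length, the one for mixed-in fibroblasts and the tests of a graded response over called genes were chosen after the results were seen. The GC and length criterion was first set on the error of a list median, which left the falls in ERBB2-high libraries open, and then on a bootstrap error, and the fibroblast test replaced a median of 8 markers, -0.21, that decided nothing. Each named gene was examined for a library far from the other 3 PHF8 shRNA libraries, by its gap to the nearest of them over the whole range. PBX2 with shRNA_1 lay at 0.626 CPM against 6.28 to 7.45 CPM (0.8292). DUSP6 with shRNA_1 lay at 195 CPM against 152 to 159 CPM (0.836). UBE2Z in the unnumbered library lay at 72.9 CPM against 86.7 to 87.3 CPM (0.954). Chance gives about 1 in 20 such genes, 6.70 of the 134 examined, and 3 were found.

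Among the 111 comparison genes tested between constructs, 2 differed: PHF8 itself was lower with shRNA_2 (log2 difference -0.92, 8.84 ± 0.173 against 16.7 ± 0.593 CPM), and so was IL1B (-1.92, 76.1 ± 4.41 against 288 ± 27.2 CPM, n = 2 each). The IL1B mean in scramble was 17.2 ± 0.497 CPM.

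The pattern weighed here is the difference between the constructs, 200 genes led by ESRP1, SPARC, MRC2, EPCAM and EREG. If these genes followed the remaining PHF8 level, the shRNA_1 and unnumbered libraries should lie off HER2 in the direction in which shRNA_2 lies off them. Set against HER2 on genes called without it, the shRNA_1 library did for 20.3% (12 of 59, SE 5.24) and the unnumbered library for 27.6% (16 of 58, SE 5.87). Among genes at a mean log2 CPM of at least 1, chosen by a 2-fold gap to shRNA_2 in one replicate number and not by a call, the library of the other number did for 33.8% (93 of 275) and 24.6% (65 of 264). A graded response alone would put each share above an even split, and each lay below it. A shift common to the shRNA_1 and unnumbered libraries enters the 2 differences with opposite signs and lowers the shares. An even split is thus not a sure reference for genes without a graded response. The shares thus gave no sign of a graded response, but they do not rule one out. PHF8 in the shRNA_1 and unnumbered libraries lay nearer to HER2 than to shRNA_2, so the shift to detect was small. Single libraries vary widely (SD 0.700 between the HER2 libraries), and no simulation of unchanged libraries was run for these shares. Over the 200 called genes, the shRNA_1 and unnumbered mean lay nearer than shRNA_2 to HER2 in 70.5% (141, SE 3.22), short of the 75% that a graded response required and above the 60% that would have spoken against it, so this share decides nothing. It replaced a same-side share of 19% (38 of 200), which is partly built in, since the same libraries enter both differences. Removing a spline on GC content and length left the median difference of the called genes at 1.36 (1.37 before), and the summed COL1A1 and COL1A2 level differed by -1.40 CPM (SE 0.767) with shRNA_2 where SPARC gained 60.1 CPM, so neither a GC or length trend nor admixed fibroblasts account for it. A graded response in part of the genes, targets other than PHF8, the history of the cultures and the missing construct number stay open. With 1 or 2 libraries per construct they cannot be separated.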

How the results depend on the processing

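Counts are given here in the order HER2 vs scramble higher and lower, PHF8 shRNA vs scramble higher and lower, PHF8 shRNA vs HER2 higher and lower (146, 125, 668, 703, 17 and 20), then genes moved back (11), genes shared in direction (232) and construct genes (200). Of the tests, the fit of the 4 PHF8 shRNA libraries alone (414 construct genes) and the one without genes resembling mitochondrial or small RNA reads (178, 126, 778, 638, 25, 21, 11, 253 and 201) were chosen after seeing the data. Counts under the other settings are listed only where they moved over 1.5 times. Without a low-count filter they were 305 and 257 (HER2 vs scramble), 183 and 162 (PHF8 shRNA vs HER2), 56 moved back, 407 shared and 640 construct genes. DESeq2 gave 518 and 359, 1167 (PHF8 shRNA vs scramble, higher), 313 and 266, 88 moved back, 610 shared and 394. The length offset gave 84 and 63, 397 and 416, 1 and 5, 2 moved back, 118 shared and 129. Upper quartile factors, the strict filter and protein-coding genes alone gave 29, 27 and 27 higher in PHF8 shRNA vs HER2, limma-voom 6 moved back, and the replicate block 379 construct genes. With 4 groups the counts were 282 and 245, 79 and 89, 30 and 418, and with only the 2 groups compared 31 and 39, 1030 higher in PHF8 shRNA vs scramble, 0 and 0 in PHF8 shRNA vs HER2, 0 moved back and 60 shared. Only shRNA_2 gave 114 and 143 against HER2, 42 moved back and 374 shared, and only the other PHF8 shRNA libraries 418 and 385 against scramble, 0 and 0 against HER2 and 0 moved back (edgeR, as above; 2784 genes at unadjusted p under 0.05 with all libraries).

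With each library left out, the counts ranged from 3 to 183 and 3 to 271, from 24 to 957 and 48 to 997, and from 0 to 740 and 0 to 584 in the 3 comparisons, from 0 to 227 moved back, from 6 to 328 shared and from 24 to 701 construct genes. Where a control group was left with 1 library, its spread was assumed to be that of the others. PHF8 in PHF8 shRNA vs scramble missed the threshold (-0.90) and passed it without a filter (-0.91), with DESeq2 (-0.88), limma-voom (-0.98) and the length offset (-0.96), and ranged from -1.08 to -0.75 with libraries left out. Lists called numbered 17, 13 and 6 in the 3 comparisons, 0, 0 and 0 with an estimated correlation and 4, 5 and 0 with fry. Log2 fold changes of the named genes, computed in 10 other settings and with each library left out, kept their direction in all of these and kept a call in most, while ZNF711, uncalled in PHF8 shRNA vs HER2, passed in 3, and of 440, 456, 216 and 208 values with a library left out (the 3 comparisons, then constructs) 175, 86, 182 and 65 no longer passed, and of 550, 570, 270 and 258 values under other settings 45, 6, 34 and 16. Across genes, the differences between replicates 1 and 2 correlated at 0.033 to 0.345 between groups. The labels give replicates of different groups only a common number, and every correlation was positive. An effect shared by replicate number is thus not excluded, and the block was run as an alternative (163 and 137, 782 and 846, 18 and 20). The cause of these moves was not tested, and no setting varied depth. All groups of a fit share 1 estimate of the spread, and the HER2 pair had the widest. A library left out can thus change the calls of a comparison that does not hold it. Fewer libraries cannot be the whole cause where some were left out, since some counts rose. At this depth and number of libraries, 40.3 to 65.7% of simulated 2-fold changes were recovered.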

Other observations

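The tests for a GC or length trend in the HER2 libraries and in the falls of ERBB2-high libraries were chosen after the results were seen, as were the naming of IL6, the simulations for the FOXO targets and the HER2 pair and the test of which HER2 library lay nearer to scramble. Among genes not in the 27 lists, 32 targets of FOXO transcription factors, which growth factor signalling through AKT is known to restrain, were lower: 32 of 32 had a negative log2 fold change in HER2 vs scramble (median -0.57, SE 0.12) and 31 of 32 in PHF8 shRNA vs scramble (median -0.63). Both comparisons use the same scramble libraries: 31 of the 32 had the same sign in both, against 21.9 on average and 26 at most in 30 simulations of unchanged libraries. The higher of the 2 medians was -0.0468 at its lowest in those simulations. They drew each gene independently, while real targets may move together within a library. A shift common to the targets in the scramble libraries could thus exceed the simulated values. Part of the agreement may come from the shared scramble libraries, which were not split, since each part would hold 1 library. Of the 32 targets, 7 and 19 were called lower and 0 higher in the 2 comparisons (11 and 26 adjusted over the list alone; camera p = 4.14e-12 and 6.12e-15, and p = 0.0229 and 0.0147 with an estimated correlation). These camera p values were not adjusted over lists, unlike those of the 27 lists, and fry was not run. Likewise unadjusted, the inflammatory cytokines and NF-kB targets gave camera p = 0.00509 and 0.00568 with an estimated correlation, and did not pass after adjustment. SESN3, an antioxidant and nutrient-sensing gene, fell 4.02-fold in HER2, TXNIP, an inhibitor of glucose uptake, 2.53-fold, BCL6 2.40-fold, FOXN3 2.06-fold, the ubiquitin ligase gene CBLB 1.99-fold, the autophagy kinase gene ULK1 1.83-fold and CITED2 2.31-fold. The median lay at -0.48 and -0.64 in HER2 replicates 1 and 2 and between -0.58 and -0.86 in the 4 PHF8 shRNA libraries.

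IL6, a cytokine gene named here after its values were seen, was at 0.0893 and 0.0419 CPM in scramble, 1.48 and 2.06 CPM in HER2, and 0.760, 1.02, 2.04 and 1.54 CPM in the shRNA_1, unnumbered and shRNA_2 libraries. The SD over genes between HER2 replicates, 0.700, exceeded the other pairs, and 12.1% of genes were over 2-fold apart, against 4.0% in the scramble pair, 7.92% between the shRNA_1 and unnumbered libraries and 3.28% in the shRNA_2 pair.

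The first pattern weighed in this part is the set of 125 genes that fell in HER2. Lower FOXO output was a hypothesis written after the falls were seen. The targets listed for it, which are outside the 27 lists, had not been examined by then. Other possible FOXO targets may have been among the falls already seen, so the hypothesis was not formed blind to these libraries. The median of -0.57 met its prediction, so lower FOXO output may account for part of these falls. The targets were tested in the same libraries that showed the falls, and 7 of them are among the 125 genes. Lower glucocorticoid receptor output stays open, with a median of -0.23 (SE 0.14) in HER2 vs scramble and -0.12 in PHF8 shRNA vs scramble over 25 targets, where the latter was nearer 0 than the prediction required. A trend with GC content or length is argued against, as the falls had a median of -1.12 after its removal and -1.13 before. The scramble shRNA itself stays untested, since the labels name it in the reference libraries alone.

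The other pattern is HER2 replicate 1 against replicate 2. Removing a spline on GC content and length, which explained 4.21% of the variance, left an SD of 0.685, above the 0.578 of the next pair, so such a trend does not account for it. Of the 546 genes over 2-fold apart at a mean log2 CPM of at least 1, 71.8% had replicate 1 on the scramble side of replicate 2. That share decides nothing, since replicate 2 enters both sides and unchanged simulated libraries gave 90.4%. Of the same genes, 39.7% (217 of 546, SE 2.09) had replicate 1 nearer than replicate 2 to the scramble mean, against 50.3% in the simulations. This argues against the lower ERBB2 level of replicate 1 as the cause for most of these genes. A part played by ERBB2 is not excluded. The simulations gave both HER2 libraries the same spread, and extra spread in replicate 1 could lower the share. No batch is named, and the history of the cultures stays open, as untested.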
